A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

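Total RNA from 8 cultures of the budding yeast Saccharomyces cerevisiae (strain name in the labels, BY4147) was measured on 8 single-colour oligonucleotide arrays, 1 per culture. The labels put the cultures in 4 groups of 2: wild type and htz1 deletion, each without added salt or harvested 20 minutes after NaCl was added to 0.4 M. The design text calls the 2 cultures of a group biological replicates. Groups and replicate numbers were taken from the sample labels.

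The scanner files hold spot intensity values read by Agilent Feature Extraction 10.7.3.1, per the file headers. Per the file headers the processed intensity was background-subtracted and detrended within its array, with no scaling between arrays, and the array design names the sacCer2 genome build. The deposited value table of the whole series holds log2 values of 6187 probes. Its column medians lay between 10.55 and 10.57, so its scale was settled by comparison with the scanner files, while the normalization behind it is not given in the sources used here. Its columns correlated across probes with the same arrays' log2 raw median signals at r = 0.987 to 0.997 and with the log2 processed signals at r = 0.95 to 0.967, and 7 of the 8 columns matched their own array best. The submitters' processing notes name limma without a version.

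Each array carried 12512 non-control spots, 2 for each of 6256 probes. Control spots and 86 spots with an outlier flag, summed over the 8 arrays, were left out, and no spot was saturated. The main values are log2 processed signals minus the array's 75th percentile over non-control spots, averaged over the spots of a probe. A gene was tested if its probe was well above background on both arrays of at least 1 group, and the brightest probe stood for a gene with several (19 of the tested genes). This left 5394 genes, of which 4843 were well above background on all 8 arrays. Gene names came from the files and from the gene table of the R64 assembly, in which 5765 probes were matched and 491 were not. The table was used for names and gene order only, because the array names another build, and 125 tested genes were not in it.

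Precision is limited by the number of arrays. The 75th percentile of the processed signal lay between 2740 and 4290 per array, and 82.2 to 88.9% of spots were well above background. In a group where a probe was not well above background on either array, the change has only a bound: it is given as "at least N-fold", from the bright group's mean and, on each dim array, the higher of the probe's own value and the lowest probe well above background.

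Gene-level tests used limma 3.58.1 in R 4.3.3: lmFit with 4 group means over all 8 arrays (4 residual degrees of freedom), contrasts and eBayes (prior degrees of freedom 3.35, prior standard deviation 0.145). The 5 comparisons were salt against no salt in each strain, deletion against wild type without and with salt, and the interaction, which is the salt response in the deletion strain minus that in wild type. Benjamini-Hochberg adjustment ran over all genes of a comparison, and adjusted p under 0.05 counts as changed. Standard errors (SE) are limma's moderated ones, on the log2 scale.

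Gene lists fixed before the data were examined were tested with camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over 37 lists, and again with a correlation estimated from the arrays and with fry. They cover osmostress, general stress, glycerol, trehalose and glycogen, oxidative stress, chaperones, cytosolic and mitochondrial ribosomes, ribosome biogenesis, RNA polymerases I and III, proteasome, respiration, glycolysis, hexose transport, galactose, phosphate, iron, ergosterol, amino acid, sulfur and purine genes, 3 cell cycle phases, histones, chromatin complexes, mating, meiosis, DNA damage, cell wall, strain markers and the neighbours of HTZ1. A planned list of genes within 20 kb of a chromosome end could not be made without coordinates of the array's build. A list of the protein-coding genes among the 10 nearest each end of a nuclear chromosome, by gene order, replaced it after the files had been seen. List members were matched by name, by synonym only where no gene bears the name, and ARG5,6 and ADE5,7 were not matched. Of all camera calls, 0 of 70 held with the estimated correlation, so that p is given beside each list. This p also rose where the estimate lay near the preset. For glycerol genes under salt in the deletion strain (estimate 0.013) the unadjusted camera p went from 4.88e-06 to 0.0109. A lost call alone therefore does not show that correlation between genes made the call. The estimate was also low for ergosterol genes (−0.029). It lay well above the preset for cytosolic ribosomal protein (0.851), ribosome biogenesis (0.471), osmostress (0.244) and general stress genes (0.203). For such lists the preset camera p assumes less correlation than was estimated, and may be too small. With fry, adjusted p under salt in wild type was 1.63e-05 for osmostress and 0.000386 for ribosome biogenesis genes. In the interaction it was 0.25 for ribosome biogenesis genes.

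The genes named in the text follow a rule fixed before the data were examined. It takes HTZ1, the 8 largest fitted rises and falls per pairwise comparison among changed genes with a standard name whose arrays did not overlap between groups and whose brighter group was well above background, the 2 changed members with the largest moderated t in the direction of each list that passed camera, 10 osmostress and cell cycle genes whatever their values, the 20 interaction genes with the largest absolute t, the strain markers and the HTZ1 neighbours. Genes outside it are said to have been chosen after their values were seen.

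All 8 arrays came from 1 slide and 1 scan. Wild-type arrays filled the first row of the slide and deletion arrays the second, and arrays without salt lay in columns 1 and 2 and arrays with salt in columns 3 and 4. Position and group therefore cannot be told apart in the 4 pairwise comparisons, and slide or scan could not be used as a block. Replicate 1 of every group lay in an odd column. The deviations of same-numbered arrays from their group means correlated across genes over all 6 pairs of groups, with r from 0.18 to 0.42. The numbers were therefore taken to pair the arrays, but only in an alternative fit with replicate as a block. The main fit has no such block, and its standard errors and p values ignore this pairing. The labels do not say where this pairing comes from. The fit with replicate as a block is given beside a named gene whose call it changes and beside a total count that it moves by over 1.5 times.

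The alternatives were normexp background correction (offset 50), quantile or median scaling, the authors' deposited values, other filters on dim probes, the mean of a gene's probes, other moderation, a fit of only the 2 groups compared, the replicate block, stricter thresholds and leaving out each array in turn. The planned normexp input, the mean signal, has no column in the files, so the median signal and median local background were used. The tests were tried on simulated data with the arrays' own means and spread: of 200 changed genes among 5394, over 20 simulations, 89.7% of those moved by 1 on the log2 scale passed in the wild-type salt comparison and 59.5% in the interaction. At 0.5 these shares were 21.3% and 3.4%, and at 2 they were 99% and 96.4%. In the unchanged comparison there were 0 false calls per simulation. Means and spread do not carry the correlation between same-numbered arrays, and 3070 genes changed under salt in wild type, against 200 here. These shares and the 0 false calls therefore describe the simulated data and need not hold for the arrays.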

Results

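Gene expression was measured by single-colour microarray in wild-type budding yeast and in a strain lacking HTZ1, which encodes a histone variant placed in promoter nucleosomes by the SWR1 complex. Cultures in exponential growth were harvested without stress or 20 minutes after addition of NaCl to 0.4 M, a hyperosmotic stress, with 2 biological replicates in each of the 4 groups. The title of the series concerns the INO80 chromatin remodelling complex and nucleosomes near promoters, and the arrays bear on how salt changes transcript levels with and without Htz1. Of 6256 probes, 5394 genes were tested. Replicates of a group correlated across genes at r = 0.987 to 0.993.

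HTZ1 itself (YOL012C) separated the strains. Its signal was well above background on all 4 wild-type arrays and on none of the 4 deletion arrays. Without salt it was at least 65.7-fold lower in the deletion strain (log2 change −8.41, SE 0.15, limma adjusted p = 3.92e-07), and with salt at least 75.5-fold lower (−8.67, SE 0.15, limma adjusted p = 3.13e-07). In wild type its transcript did not pass the test for a salt change (−0.28, SE 0.15, limma adjusted p = 0.155). Of the genes beside HTZ1, HRD1 (0.29 without salt, 0.09 with salt), PLB3 (0.21 and 0.14) and YOL014W (0.15 and 0.71) did not pass in either deletion comparison, although YOL014W passed with salt under the replicate block (adjusted p = 0.0459). RCL1, which acts in rRNA processing, was at −0.25 (SE 0.20) in the deletion strain against wild type without salt and did not pass. With salt RCL1 was lower in the deletion strain by 1.61 (SE 0.20) and passed, being well above background on 1 of the 2 deletion arrays. The marker genes HIS3, LEU2, URA3 and MET17 were not well above background on any array. LYS2, TRP1 and ADE2 were detected and passed in neither deletion comparison, except LYS2 without salt under the replicate block (adjusted p = 0.0282).

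In wild type, salt raised the genes of glycerol production and uptake, reserve carbohydrates and general stress defence, and lowered those for making ribosomes. STL1, the glycerol/proton symporter, rose at least 307-fold. GPD1, the glycerol-3-phosphate dehydrogenase of osmoadaptation, rose 26-fold (4.70, SE 0.14, limma adjusted p = 5.3e-07), GPP2, a glycerol phosphatase, 120-fold (6.91, SE 0.14), and its paralog GPP1 1.96-fold (0.97, SE 0.20). The sodium pump gene ENA1 rose 5.47-fold (2.45, SE 0.18). Of 33 Hog1-linked osmostress genes 31 rose and 0 fell, with a median log2 change of 3.48, or 3.29 with 8 members set at their bound (camera adjusted p = 8.04e-17, adjusted p = 0.17 with an estimated correlation). They include the catalase CTT1 (6.13, SE 0.19), the aldehyde dehydrogenase ALD3 (7.37, SE 0.20), the reductase GRE2 (4.31, SE 0.29) and RTC3, which rose at least 260-fold. Of 45 general stress genes, 43 rose and 0 fell, with a median of 3.36, or 3.12 with 5 members at their bound (camera adjusted p = 6.32e-21, adjusted p = 0.17 with an estimated correlation). The membrane-stabilising heat shock gene HSP12 rose 194-fold and the hexokinase gene HXK1 75.2-fold, and SOL4 of the pentose phosphate pathway rose at least 119-fold. Of 21 trehalose and glycogen genes 19 rose (median 3.02, adjusted p = 0.17 with an estimated correlation), among them the glycogen synthase GSY1 (5.69, SE 0.13) and the trehalose phosphatase TPS2 (4.94, SE 0.12). Of 16 glycerol genes 11 rose and 2 fell (median 1.04, adjusted p = 0.17 with an estimated correlation). The pentose phosphate gene NQM1 rose 204-fold, TKL2 of the same pathway at least 68.9-fold and the hexose transporter gene HXT5 at least 81.3-fold. In these 4 lists, and wherever a single count is given, the counts adjusted over the list alone were the same.

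All 92 ribosome biogenesis genes fell in wild type under salt, with a median log2 change of −2.26 (camera adjusted p = 1.43e-31, adjusted p = 0.299 with an estimated correlation). LTV1 fell by 3.21 (SE 0.14) and FAF1 by 3.29 (SE 0.16), and the rRNA processing genes RRP12, DHR2 and PUF6 fell as well. Of 21 subunits of RNA polymerases I and III 20 fell, or 21 adjusted over the list alone (median −1.57, adjusted p = 0.17 with an estimated correlation), with RPA43 at −3.00 (SE 0.18) and RPC25 at −2.46 (SE 0.13). Of 136 cytosolic ribosomal protein genes 119 fell and 1 rose, or 122 and 1 adjusted over the list alone, by a smaller median of −0.89 (adjusted p = 0.513 with an estimated correlation). The phosphate transporter gene PHO84 fell 57.1-fold and the adenine deaminase gene AAH1 18.5-fold. Amino acid synthesis genes (27 of 44 fell and 2 rose, or 29 and 3 adjusted over the list alone; LEU9 −2.58, LYS4 −2.04), ergosterol genes (14 of 25 fell and 2 rose; ERG11 −1.63) and phosphate genes (12 of 17 fell and 3 rose, or 12 and 4 adjusted over the list alone; PHO12 −2.61) also passed camera. So did purine genes, of which 11 of 15 fell and 1 rose, or 11 and 2 adjusted over the list alone (IMD4 −1.96, GUA1 −1.36). With an estimated correlation these 4 lists had adjusted p = 0.17, 0.17, 0.427 and 0.513. The fatty acid desaturase OLE1 fell by 3.52 (SE 0.77), and the mating-type endonuclease HO fell by 3.74 (SE 0.52). OLE1 and PUF6 were well above background on 1 of the 2 salt arrays.

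Smaller groups moved as well in wild type. Of 34 proteasome genes 20 rose, or 21 adjusted over the list alone (median 0.39; RPN5 0.74, SE 0.11), 14 of 38 respiratory chain genes rose and 2 fell (median 0.33; COX5B 2.73, SDH1 2.25), and 10 of 15 DNA damage genes rose (median 0.60; DDR48 2.17, MAG1 1.46). With an estimated correlation their adjusted p values were 0.513, 0.595 and 0.402. Of 35 G1/S cell cycle genes 14 fell and 6 rose, or 16 and 7 adjusted over the list alone (median −0.32; NRM1 −1.86, POL12 −1.21), while the G1 cyclin gene CLN2 was at 0.12 (SE 0.30) and did not pass. Of 21 M/G1 genes 11 fell and 1 rose, or 12 and 1 adjusted over the list alone (SUN4 −1.90, AMN1 −1.24), and of 22 sulfur genes 9 fell and 2 rose, or 8 and 2 adjusted over the list alone (SAM1 −1.38; MMP1 fell at least 4.6-fold). These 3 lists had adjusted p = 0.486, 0.513 and 0.513 with an estimated correlation. Of 10 hexose transport genes 8 rose and 1 fell (HXT1 2.82, SE 0.21), and of 6 galactose-linked genes 5 rose, led by PGM2 (5.70), a phosphoglucomutase that also serves glycogen synthesis, and GCY1 (2.07), a glycerol dehydrogenase. Of 9 meiosis genes tested 6 rose, with SPS100 up at least 8.2-fold and SPS19 at 1.35. Not tested were 25 meiosis, 9 hexose transport and 3 galactose-linked members. A gene dim in unstressed wild type was tested only if it was bright in another group, which favours rising genes in these lists. Of 9 canonical histone genes 4 fell, or 2 adjusted over the list alone, with HTA1 at −0.90 and HTA2 at −0.57. These 4 lists had adjusted p = 0.459, 0.402, 0.459 and 0.595 with an estimated correlation. HTA2 did not pass after quantile scaling (−0.20), in the authors' values (−0.21) or without wild-type unstressed replicate 1 (−0.54).

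In total 3070 of 5394 genes changed in wild type under salt by limma, 1683 higher and 1387 lower, and 1303 of them by at least 2-fold. Genes with near-identical copies, such as ribosomal protein, histone, hexose transporter, ENA and PHO11/PHO12 genes, may share probe signal. Some list medians moved by over 1.5 times: to 1.91 for trehalose and glycogen, 0.98 for hexose transport, 0.46 for galactose-linked, 0.23 for meiosis and −0.21 for histone genes in the authors' values, and to −0.52 for cytosolic ribosomal protein genes with quantile scaling. Hexose transport (0.15) and meiosis genes (0.14) did not pass camera with no filter on dim probes, nor did sulfur genes (−0.23) without wild-type salt replicate 2. Position on the slide went with treatment, with salt arrays in columns 3 and 4.

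The deletion strain gave a response of the same kind. Salt changed 3149 of 5394 genes by limma, 1582 higher and 1567 lower, and 1354 by at least 2-fold. All 33 osmostress genes rose (median 3.45, adjusted p = 0.157 with an estimated correlation), with STL1 up at least 446-fold, GPD1 up 19.6-fold (4.30, SE 0.14, limma adjusted p = 1.04e-06), CTT1 at 6.64 (SE 0.19), ALD3 at 7.35 (SE 0.20) and GRE1 at 5.47 (SE 0.12; 1 of the 2 unstressed arrays well above background). Of 45 general stress genes 43 rose (median 3.04, adjusted p = 0.157 with an estimated correlation), with SOL4 at 6.09, HSP12 at 5.91 and MSC1 at 5.34. Of 21 trehalose and glycogen genes 20 rose (median 3.25; TPS2 4.65, GSY1 4.58), and of 16 glycerol genes 12 rose and 1 fell, or 13 and 1 adjusted over the list alone (GPP2 5.43), both with adjusted p = 0.157 with an estimated correlation. FMP45 rose at least 69.2-fold, FMP48 at least 34-fold and TKL2 at least 103-fold.

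All 92 ribosome biogenesis genes fell in the deletion strain too, with a median of −3.16 (camera adjusted p = 4.29e-32, adjusted p = 0.292 with an estimated correlation). The nucleolar genes NSR1 (−4.48, SE 0.22) and SPB1 (−4.52, SE 0.32) and the ribosome assembly gene RRS1 (−4.38, SE 0.18) fell, and IMP3 and RRP36, not well above background after salt, fell at least 6.79-fold and 11.7-fold. Of the 21 polymerase I and III subunits 20 fell, or 21 adjusted over the list alone (median −2.21; RPC25 −3.85, RPA12 −3.62; adjusted p = 0.166 with an estimated correlation). Of 136 cytosolic ribosomal protein genes 125 fell, or 128 adjusted over the list alone with 1 higher (median −0.89; RPL7B −2.10; adjusted p = 0.608 with an estimated correlation). Of 35 G1/S genes 22 fell and 1 rose (median −0.80; POL30 −1.71, POL12 −1.56; adjusted p = 0.311 with an estimated correlation), and 16 of 22 sulfur genes fell and 3 rose (median −0.86; MHT1 −2.54, SAM1 −1.44; adjusted p = 0.441 with an estimated correlation). Amino acid (26 of 44 fell and 1 rose), ergosterol (16 of 25 fell and 1 rose), phosphate (12 of 17 fell and 2 rose) and histone genes (6 of 9 fell), and respiratory (19 of 38 rose and 2 fell), hexose transport (7 of 10 rose and 1 fell), galactose-linked (4 of 6 rose) and DNA damage genes (8 of 15 rose) also passed camera, with adjusted p from 0.157 to 0.659 with an estimated correlation. CLN2 fell by 0.98 (SE 0.30), but did not pass without deletion unstressed replicate 2 (−0.65) or without deletion salt replicate 1 (−0.62). HTZ1 was not well above background in either deletion group, and GAL7, which was not well above background without salt and rose at least 1.5-fold, turned to −0.19 under normexp, where 775 genes rose and 1404 fell.

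In the authors' values the medians in the deletion strain were 0.52 for galactose-linked, 0.85 for hexose transport, −0.53 for G1/S and −0.41 for histone genes, and hexose transport genes (0.53) did not pass camera with no filter.

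Across genes, the log2 salt responses of the strains correlated at Pearson r = 0.94 and Spearman rho = 0.932, with genes not being independent replicates. Both strains shared 1377 rising genes, against 494 expected of independent lists, and 1257 falling genes, against 403 expected, in comparisons that share no array. Both comparisons set the same columns of the slide against each other, so an effect of column would enter both. The total overlap of 2634 was 1667 under normexp.

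**Figure D1:**
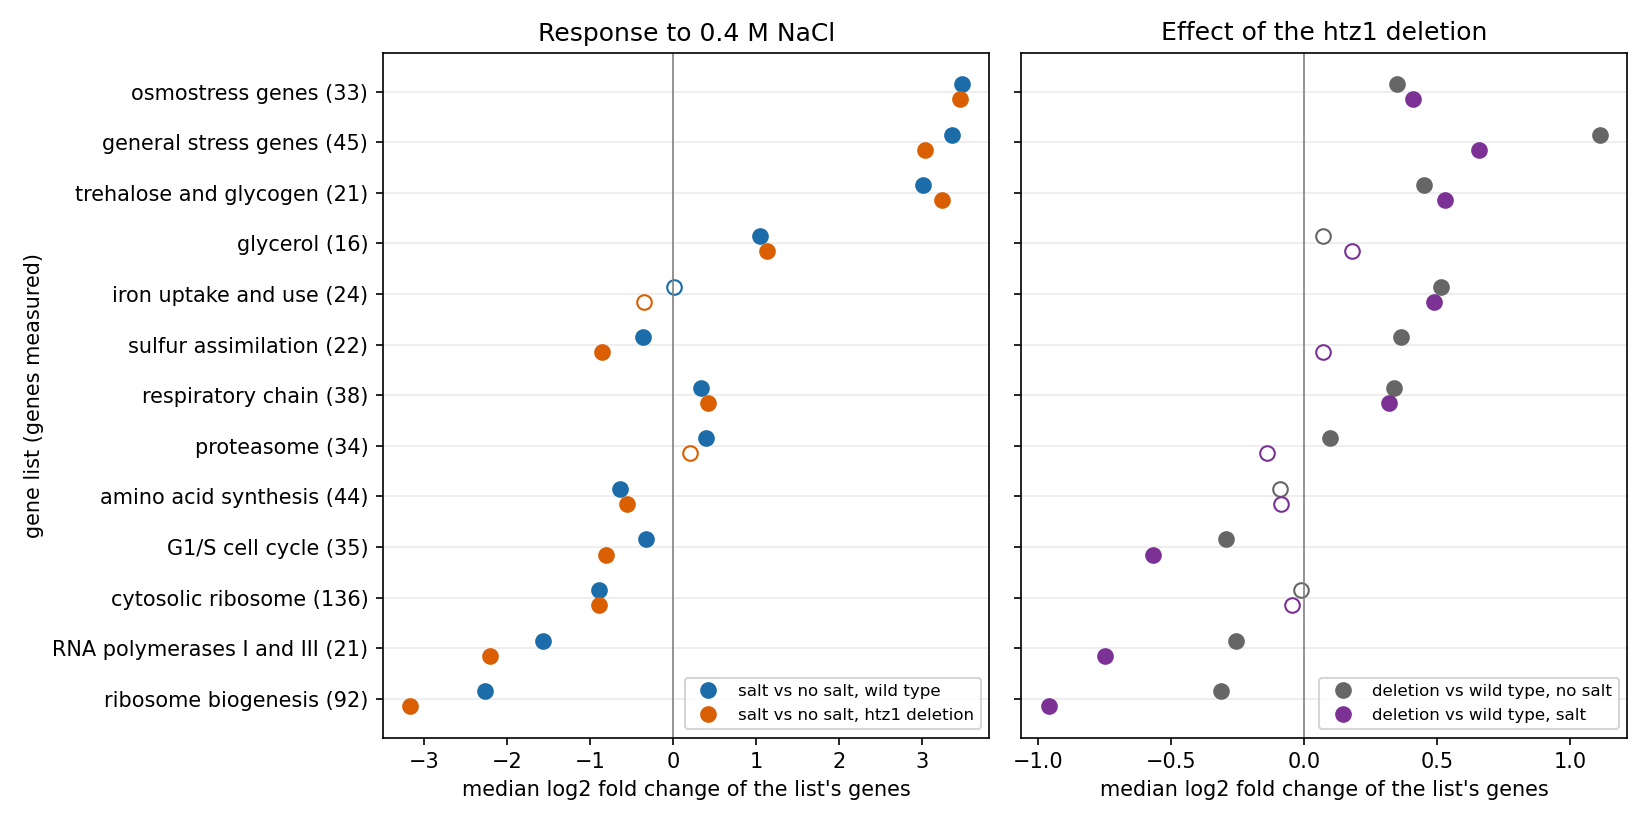
Median log2 fold change of the genes in 13 lists, with the number of genes measured in brackets. The left panel shows salt against no salt in wild type (blue) and the deletion strain (orange), and the right panel deletion against wild type without salt (grey) and with salt (purple). Filled points passed camera with preset correlation, and none of them passes with an estimated one. Ribosome biogenesis lies at −2.26 and −3.16 on the left, and general stress genes at 1.11 without salt on the right.

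Without salt, the deletion strain had higher general stress, iron and sulfur gene expression than wild type. Of 45 general stress genes 32 were higher and 0 lower, or 37 and 0 adjusted over the list alone, with a median log2 difference of 1.11 (camera adjusted p = 4.79e-25, adjusted p = 0.551 with an estimated correlation), or 0.635 in the authors' values. HXK1 was 12.9-fold higher (3.69, SE 0.13, limma adjusted p = 2.56e-05), the small heat shock gene HSP26 9.76-fold (3.29, SE 0.16), and HSP12 4.37-fold (2.13, SE 0.18). RTC3 was at least 5.57-fold higher, and DDR2, TMA10, YGP1, SPG4 and HXT5 were higher too. Of 33 osmostress genes 11 were higher, or 15 with 1 lower adjusted over the list alone (median 0.35), and of 21 trehalose and glycogen genes 10 were higher, or 12 adjusted over the list alone (median 0.45; TSL1 2.53, GLC3 1.64), both with adjusted p = 0.554 with an estimated correlation. Of 24 iron regulon genes 12 were higher and 0 lower, or 14 adjusted over the list alone (median 0.51), including FIT2 (2.47, SE 0.19) and FIT3 (2.41, SE 0.19), cell wall mannoproteins of siderophore iron uptake. Of 22 sulfur genes 8 were higher, or 10 adjusted over the list alone (median 0.36), with MET2 at 1.28 and the ATP sulfurylase MET3 at 1.07. The iron and sulfur lists had camera adjusted p = 1.1e-07 and 0.000378, and adjusted p = 0.554 with an estimated correlation.

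Single genes also fell in the unstressed deletion strain. The sterol importer gene PDR11 was at least 2.65-fold lower, MCO32 at least 2.72-fold, the biotin synthesis gene BIO4 at least 3.57-fold and GUP2 at least 2.33-fold, and SOM1, detected in both strains, was 6.24-fold lower (−2.64, SE 0.13, limma adjusted p = 0.000111). The ends of chromosomes hold DSF1, PRM9 and MST28, at least 1.57-fold, 1.33-fold and 1.68-fold lower. Under normexp these calls were all lost: PDR11 was at −0.46, MCO32 at −0.33, BIO4 at −0.82, GUP2 at −0.12, MST28 at −0.10 and SOM1 at −1.47, and PRM9 and DSF1 turned to 0.15 each. In all, 19 of the 37 genes named in this comparison that passed did not pass there. Of 92 ribosome biogenesis genes 3 were lower, or 0 adjusted over the list alone (median −0.31; DBP2 −0.51, SDA1 −0.52), and of 35 G1/S genes 5 were lower, or 6 adjusted over the list alone (median −0.29; the S-phase cyclin CLB6 −1.36, the primase PRI1 −0.55). Of polymerase I and III genes 2 were lower (RPC37 −0.73, RPC82 −0.65), and of 32 other chromatin genes 3 were lower (RPD3 −0.62, SWI3 −0.63). These 4 lists had adjusted p = 0.752, 0.554, 0.692 and 0.702 with an estimated correlation. Respiratory (5 higher and 1 lower, or 6 and 1 adjusted over the list alone; COX5B 1.61, CYT1 0.67), phosphate (3 higher; PHM8 at least 4.2-fold, and the glycerol phosphatase GPP2 1.39), glycolysis (1 higher; TDH1 1.5) and proteasome genes (0 changed, median 0.10) passed camera upwards, with adjusted p from 0.554 to 0.775 with an estimated correlation.

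The medians were 0.145 for osmostress and 0.285 for trehalose and glycogen genes in the authors' values, against 0.78 and 0.98 under normexp, where G1/S was at −0.13 and other chromatin genes turned to 0.01. Other chromatin (−0.09), glycolysis (0.14), phosphate (0.20) and proteasome genes (0.03) did not pass camera without deletion unstressed replicate 1, nor did other chromatin (−0.12) and proteasome genes (0.04) without wild-type unstressed replicate 2.

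Altogether 738 genes differed between the unstressed strains by limma, 397 higher and 341 lower in the deletion strain, and 206 by at least 2-fold, against 1390 with the replicate block, 348 with only the 4 unstressed arrays in the fit and 185 under normexp, of which 162 were higher and 23 lower. The count was 270 without wild-type unstressed replicate 1 and 285 without replicate 2, and BIO4, CLB6, CYT1, DBP2, HXT5, MST28, PRI1, RPC37, RPC82, RPD3, SDA1 and SWI3 each missed the threshold in at least 1 fit that left out an array (HXT5 2.78 and MST28 −1.80 without replicate 1).

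With salt, ribosome biogenesis, RNA polymerase and G1/S genes were lower in the deletion strain than in wild type. Of 92 ribosome biogenesis genes 70 were lower and 0 higher, or 78 adjusted over the list alone, with a median of −0.96 (camera adjusted p = 8.77e-21, adjusted p = 0.463 with an estimated correlation). IMP3 was at least 2.19-fold lower and RRP36 at least 2.73-fold, and UTP13, detected in both strains, was 5.28-fold lower (−2.40, SE 0.21, limma adjusted p = 0.000886). Of 21 polymerase I and III genes 16 were lower, or 17 adjusted over the list alone (median −0.75; RPA12 −2.26, SE 0.15; RPC37 −1.61, SE 0.14; adjusted p = 0.463 with an estimated correlation). Of 35 G1/S genes 20 were lower, or 26 adjusted over the list alone (median −0.57, adjusted p = 0.41 with an estimated correlation), with the cyclin gene PCL1 3.95-fold lower, CLB6 at least 2.44-fold and the cohesin gene MCD1 2.46-fold. PDR11 was at least 4.35-fold lower, MST28 at least 2.46-fold, AIR1 at least 5.41-fold, and SOM1 and RRT14 were 6.14-fold and 5.78-fold lower, RRT14 being well above background on 1 of the 2 deletion arrays.

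General stress, osmostress, reserve carbohydrate and iron genes were higher in the salt-treated deletion strain than in salt-treated wild type. Sulfur genes did not pass with salt (3 of 22 higher and 2 lower, median 0.07, camera adjusted p = 0.0508). Of 45 general stress genes 27 were higher and 1 lower, or 32 and 1 adjusted over the list alone (median 0.66; HSP26 2.31, HXK1 1.01; adjusted p = 0.41 with an estimated correlation). Of 33 osmostress genes 11 were higher, or 13 adjusted over the list alone (median 0.41; RTN2 1.1, TFS1 1.00; adjusted p = 0.463 with an estimated correlation), and of 21 trehalose and glycogen genes 10 were higher and 1 lower, or 14 and 1 adjusted over the list alone (median 0.53; TPS2 0.81, UGP1 0.72; adjusted p = 0.41 with an estimated correlation). Of 24 iron genes 10 were higher (median 0.49; FIT2 2.17, FIT3 2.00; adjusted p = 0.47 with an estimated correlation). PHO84 was 6.81-fold higher (2.77, SE 0.38), the polyamine transporter gene TPO2 11.3-fold (3.5, SE 0.67) and MGA1 at least 3.04-fold. HSP30, well above background on 1 of the 2 wild-type arrays, was higher by 3.41 (SE 0.31). TPO2 stood at 3.01 without wild-type salt replicate 1, where it did not pass. Respiratory (4 higher and 1 lower, or 3 and 1 adjusted over the list alone; COX5B 0.71, NDI1 0.62), phosphate (5 higher; PHO5 0.73), oxidative stress (4 higher and 1 lower, or 4 and 2 adjusted over the list alone; TSA2 1.12, GRX1 0.80), glycolysis (1 higher; TDH1 1.17) and M/G1 genes (1 higher, 2 lower, median 0.34; AMN1 0.52) also passed camera upwards, with adjusted p from 0.463 to 0.661 with an estimated correlation. The glycolysis median turned to −0.01 in the authors' values, against 0.16.

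In the authors' values the medians were −0.49 for ribosome biogenesis, −0.43 for polymerases I and III, −0.255 for G1/S and 0.245 for osmostress genes. Under normexp 10 of the 36 genes named in this comparison that passed did not, among them PDR11 (−1.91), MST28 (−1.75), CLB6 (−1.15) and MGA1 (1.47). Oxidative stress genes (0.05) did not pass camera without wild-type salt replicate 2.

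Together 1182 genes differed under salt by limma, 311 higher and 871 lower in the deletion strain, and 298 by at least 2-fold. The split depended on the processing: it was 424 and 564 with quantile scaling, 601 and 503 with median scaling, and 549 and 627 in the authors' values. The count was 1826 with the replicate block and 324 under normexp, and 786 and 457 without wild-type salt replicates 1 and 2, and 438 and 497 without deletion salt replicates 1 and 2. AMN1, COX5B, GRX1, NDI1 and PHO5 each missed the threshold without at least 1 of these arrays, with AMN1 at 0.38 without wild-type salt replicate 1, and COX5B at 0.54, GRX1 at 0.70, NDI1 at 0.53 and PHO5 at 0.60 without replicate 2.

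The deletion effects without and with salt correlated across genes at Pearson r = 0.695 and Spearman rho = 0.724, in comparisons that share no array. They had 189 higher genes in common, against 22.9 expected of independent lists, and 241 lower genes, against 55.1 expected. Both comparisons set the same rows of the slide against each other, and same-numbered arrays deviated together (r from 0.18 to 0.42). The expected numbers assume an independence that these comparisons need not have. The total of 430 was 879 with the replicate block, 214 with only the arrays compared and 65 under normexp. Without 1 array it was 154 and 156 (wild-type unstressed replicates 1 and 2), 188 (wild-type salt replicate 2), and 179 and 191 (deletion salt replicates 1 and 2).

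The interaction asked directly whether the salt response differed between the strains. It passed for 54 genes by limma, with a lower fitted response in the deletion strain for 48 and a higher one for 6. Some of the 48 rose less in the deletion strain. HXK1 rose 75.2-fold in wild type and 11.7-fold in the deletion strain (difference −2.68, SE 0.19, limma adjusted p = 0.00634), and TMA10 46.8-fold and 8.11-fold (−2.53, SE 0.22). RTC3 rose at least 260-fold in wild type, where it was not well above background without salt, and 72.1-fold in the deletion strain (−2.95, SE 0.23). The glucokinase gene GLK1 (−1.65), GPP2 (−1.49), HSP12 (−1.69), CPP3 (−2, 1 of the 2 unstressed wild-type arrays well above background) and SOL4 (−1.62, not well above background in unstressed wild type) behaved alike, and all 8 rose in both strains. These 8 genes were higher in the unstressed deletion strain than in unstressed wild type, RTC3 by at least 5.57-fold, SOL4 by at least 3.32-fold and the other 6 by 1.39 (GPP2) to 3.69 (HXK1) on the log2 scale. Others fell further: RRT14 fell 5.55-fold and 25.5-fold (−2.20, SE 0.19), RPA12 2.97-fold and 12.3-fold (−2.05, SE 0.21) and RPC25 5.5-fold and 14.5-fold (−1.40, SE 0.18). The fold falls of IMP3 (−2.30), RRP36 (−1.93), AIR1 (−1.72) and YNL162W-A (−1.79) are bounds in the salt-treated deletion strain, and UTP11 was at −1.47. PCL1 rose 2.97-fold in wild type and was at −0.06 in the deletion strain (difference −1.64, SE 0.20), and YGR073C rose in wild type and fell in the deletion strain (−1.77). ATF1, an alcohol acetyltransferase gene, fell in wild type and rose in the deletion strain (1.23, SE 0.16). YNL195C (2.44) and MCO32 (1.59) were not well above background in the unstressed deletion strain. YHR022C (fitted difference 2.29) was not well above background in either strain without salt, so both of its responses are bounds and the direction of their difference is not settled.

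By list, the interaction medians were −0.72 for ribosome biogenesis, where 7 of 92 genes passed, −0.51 for general stress (8 of 45), −0.50 for polymerases I and III (2 of 21) and −0.36 for G1/S (1 of 35), all lower. In the authors' values these medians were −0.218, −0.26, −0.115 and −0.175. The counts adjusted over the list alone were 44, 20 with 2 higher, 8 and 9. Camera adjusted p values were 3.81e-19, 1.04e-06, 2.31e-05 and 4e-05, with adjusted p = 0.902 for each with an estimated correlation. Proteasome (−0.23), purine (0.23) and M/G1 genes (0.33) passed camera with 0 members changed, and had adjusted p = 0.977, 0.902 and 0.902 with an estimated correlation. Purine and M/G1 genes did not pass camera without wild-type salt replicate 1 (0.08 and 0.07) or deletion salt replicate 2 (0.09 and 0.11), nor did proteasome genes (−0.12) without deletion unstressed replicate 1. The osmostress list had a median interaction of 0.08 (camera adjusted p = 0.677, fry adjusted p = 0.87), and its sign turned with the processing, to −0.02 with quantile scaling and −0.28 under normexp. Of its 33 genes 3 passed, all lower: RTC3 (−2.95), HSP12 (−1.69) and GPP2 (−1.49). Adjusted over the list alone, 5 were lower and 3 higher. CTT1 (0.52), ENA1 (0.32), GPP1 (0.12), ALD3 (−0.02), TPS2 (−0.29), GPD1 (−0.41) and CLN2 (−1.11) did not pass, nor did STL1 (fitted difference 0.23), whose responses are bounds in both strains so that their difference is not settled, and GRE2 (−0.86) passed only with the replicate block (adjusted p = 0.0495).

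Of the 54 interaction genes, 36 were well above background on all 8 arrays, and of the 6 with a higher fitted response in the deletion strain only ATF1 was, so that parts of these differences have only bounds. The count was 141 with the replicate block, 30 with median scaling, 19 in the authors' values (6 higher and 13 lower), 14 with no filter on dim probes and 1 under normexp, and of the 22 genes named here that passed, 13 did not in the authors' values (IMP3 −0.21, RRP36 −0.39, AIR1 −0.26, SOL4 −0.05, MCO32 0.16). Under normexp MCO32 turned to −0.69 and YHR022C to −0.03. Without 1 array the count was 13 and 19 (wild-type unstressed replicates 1 and 2), 102 and 16 (wild-type salt), 21 and 20 (deletion unstressed), and 4 and 14 (deletion salt), and 18 of the 22 did not pass without deletion salt replicate 1.

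**Figure D2:**
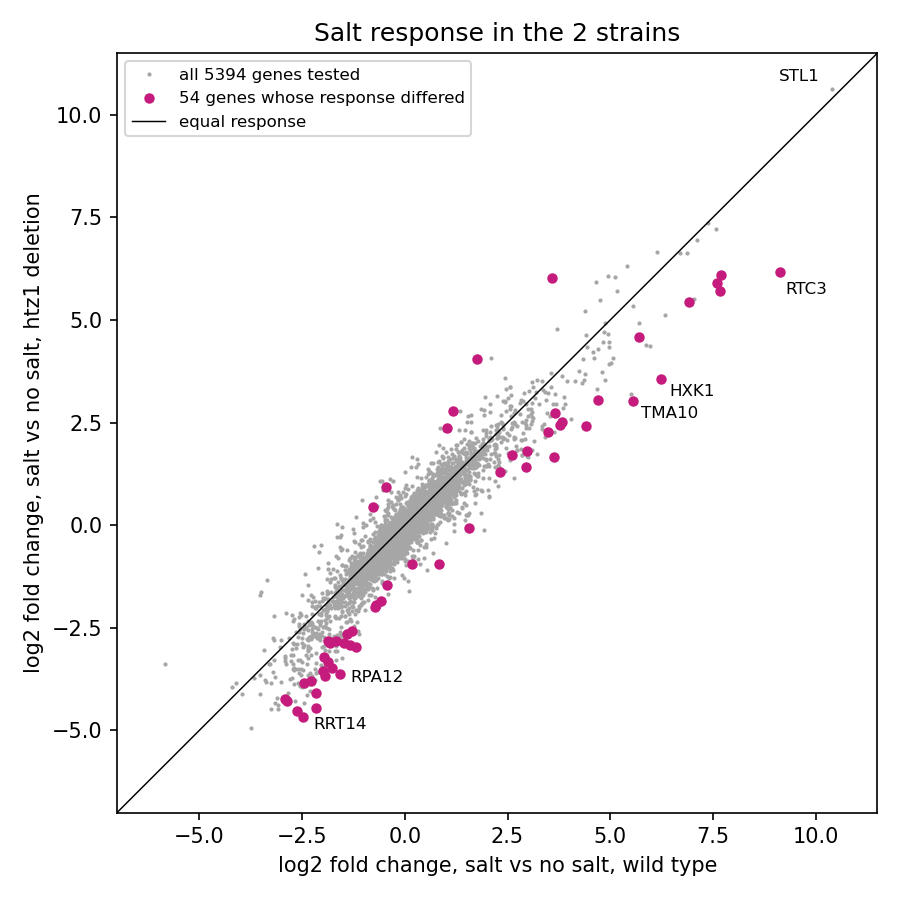
Log2 fold change of each gene with salt in the deletion strain (vertical axis) against wild type (horizontal axis). Grey dots are the 5394 genes tested, magenta points the 54 whose response differed by the interaction test, and the line marks equal responses. RTC3, HXK1 and TMA10 lie below the line among rising genes, and RRT14 and RPA12 below it among falling genes.

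**Figure D3:**
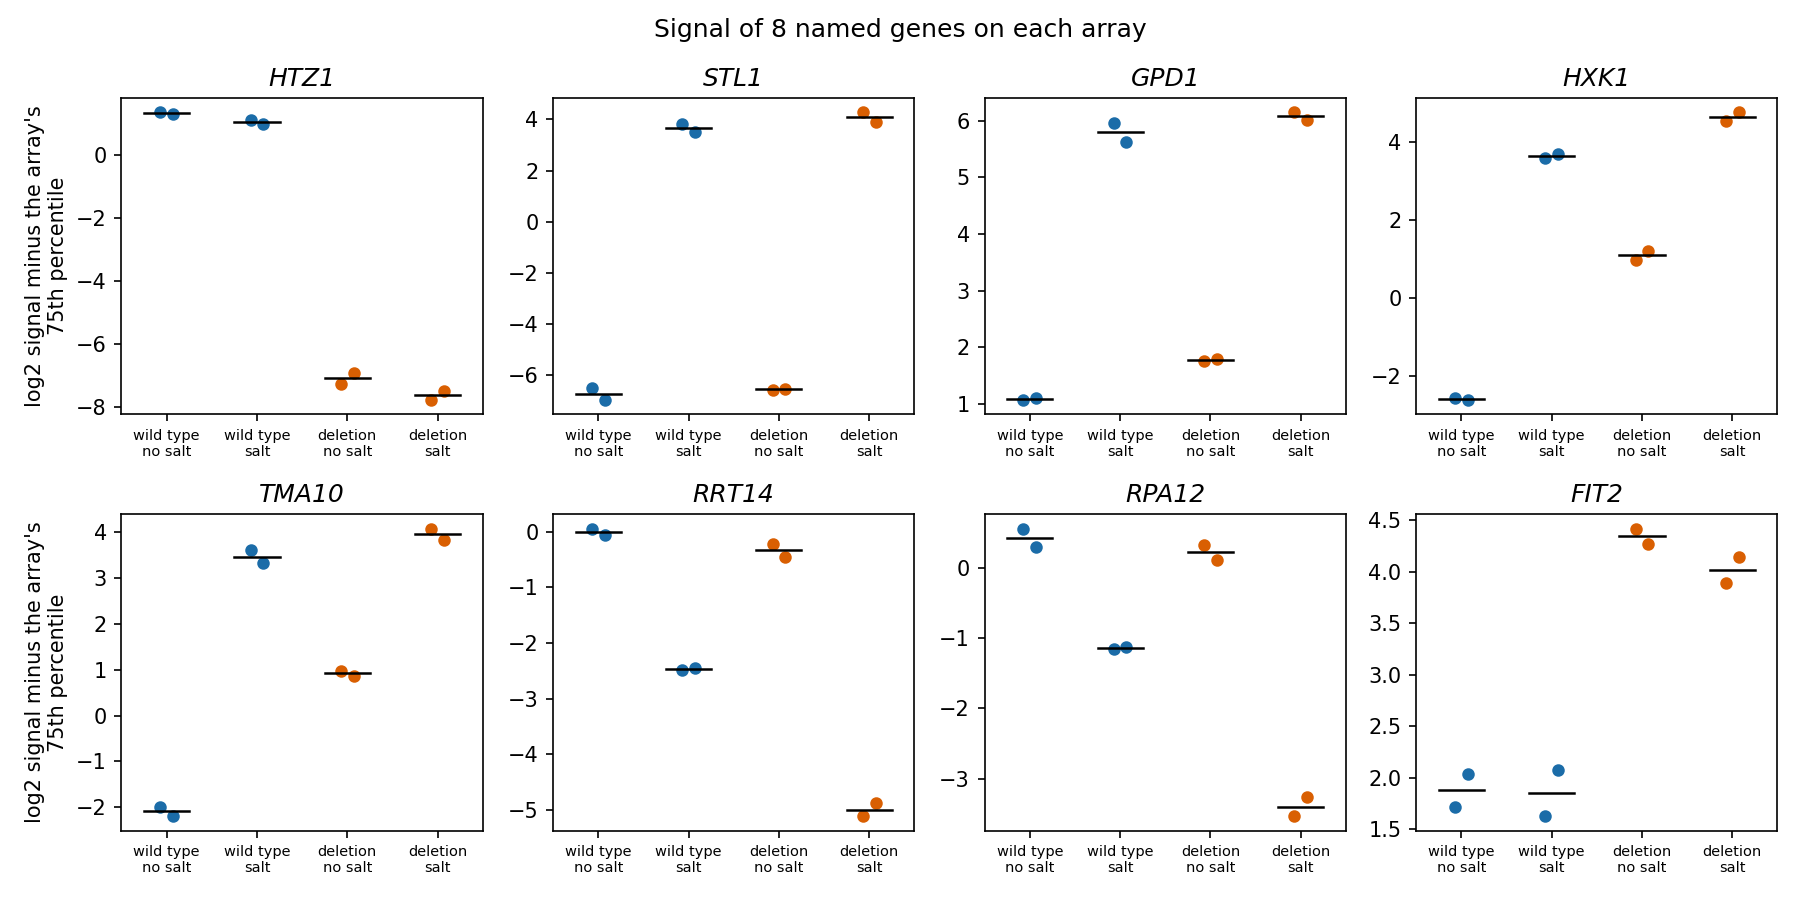
Log2 signal minus the array's 75th percentile for 8 named genes on each of the 8 arrays, wild type in blue and deletion strain in orange, with black bars at the mean of the 2 arrays of a group. HTZ1 is low on all 4 deletion arrays, and HXK1 and TMA10 start higher in the unstressed deletion strain and end at levels nearer those of wild type after salt.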

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

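The tests of mixed RNA, of scaling, of another signal and of a stronger overall response were chosen after the results they bear on had been seen, and those of a single culture, of background and of slide position before.

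The salt response differed between the strains in 54 genes by the interaction test, among 5394 tested, and the differences below are log2 responses in the deletion strain minus wild type. Of the named ones, YNL195C (2.44) and ATF1 (1.23) responded more positively in the deletion strain, as did MCO32 (1.59) in the main values. YNL195C and MCO32 were not well above background in the unstressed deletion strain. MCO32 turned to −0.689 under normexp and was at 0.16 in the authors' values, so its direction depends on the processing. The fitted value of YHR022C (2.29) has no settled direction, because the gene was not well above background in either strain without salt. RTC3 (−2.95), HXK1 (−2.68), TMA10 (−2.53), CPP3 (−2), HSP12 (−1.69), GLK1 (−1.65), SOL4 (−1.62) and GPP2 (−1.49) rose less there. All of these started higher in the unstressed deletion strain, and none was called lower there after salt. With salt HXK1 (1.01), SOL4 (0.93), RTC3 (0.62) and GLK1 (0.51) were higher in the deletion strain, and TMA10, CPP3, HSP12 and GPP2 did not pass. IMP3 (−2.3), RRT14 (−2.2), RPA12 (−2.05), RRP36 (−1.93), YNL162W-A (−1.79), AIR1 (−1.72), UTP11 (−1.47) and RPC25 (−1.4) fell further. YGR073C (−1.77) and PCL1 (−1.64) rose in wild type and did not rise in the deletion strain. Gene lists differed by camera with a preset correlation, and none with an estimated one: general stress (median −0.515), ribosome biogenesis (−0.72), RNA polymerases I and III (−0.505), proteasome (−0.234), purine (0.227), G1/S (−0.356) and M/G1 genes (0.327).

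General stress genes were higher in the unstressed deletion strain than in unstressed wild type, with a list median of 1.11. RNA from salt-treated cells mixed into these samples would raise each salt-induced gene by the same share of its gain. The median share was 1.27% for 29 osmostress genes outside the general stress list (quartiles 0.119 and 4.44%). It was 6.66% for 39 general stress genes outside the osmostress list (quartiles 4.17 and 12.1%). This difference argues against such mixing as the whole explanation (two-sided permutation test over genes, p = 0.00197). Genes are not independent and all shares come from the same cultures, so this p does not cover variation between cultures. Scaling between arrays, another signal and its processing, and a single culture are argued against as whole explanations, since the lowest median was 1.09 with quantile or median scaling, 0.635 in the authors' values or under normexp, and 0.966 without 1 unstressed array (deletion replicate 2). Position on the slide cannot be told apart from genotype, as 0 slide rows held both, and so an effect of lacking Htz1 on stress genes before any stress may account for the pattern, as may position. Other differences shared by both unstressed deletion cultures were not tested.

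Ribosome biogenesis genes fell further under salt in the deletion strain, with an interaction median of −0.72. Signal near the background is argued against, because the median was −0.667 in the 46 brighter members, and so, in the values used here, is a stronger response of every salt-responsive gene: the median response in the deletion strain was 0.998 times that in wild type for cytosolic ribosomal proteins and 0.992 times for osmostress genes, against 1.4 times for ribosome biogenesis and 1.41 times for polymerases I and III. Scaling between arrays alone is argued against as the whole explanation (−0.535 with quantile and −0.608 with median scaling), but another signal and its processing stay open: the median was −0.626 under normexp and −0.218 in the authors' values, where the ribosome biogenesis response was only 1.1 times that in wild type (−2.12 against −1.92) and the osmostress one 1.05 times. Position stays open too, since 0 slide rows held both genotypes, although an effect that adds the same amount to all arrays of a row would cancel in the interaction. A loss of Htz1 may deepen this fall, but the size of the difference depends on the values used.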

How the results depend on the processing

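Each alternative here was chosen before the data were examined, except that normexp used median signals. The 231 values of named genes made 4053 pairs of a value and an alternative. Of these pairs 3792 kept direction and side of the threshold, 212 no longer passed, 10 passed newly and 39 changed sign. The 71 list results made 1207 such pairs with the preset correlation, and there these numbers were 1133, 65, 0 and 9. The pooled numbers hide differences between comparisons: of 22 named interaction calls 21 were lost in at least 1 alternative. With an estimated correlation 0 of 70 list calls held, and without 1 array 65 to 74 lists were called. The replicate block gave 1390 genes for the deletion without salt, 1826 with salt, 141 for the interaction and 879 in the deletion overlap. For salt it gave 3572 genes in wild type and 3615 in the deletion strain, within 1.5 times the counts without it. It also added LYS2, YOL014W and GRE2 in the comparisons named above, and it changed no other call of a named gene and ended no list call. Slide or scan as a block was not run, because there was 1 of each. Signal over background limits the dim genes, and the cause of the changes below was not tested, except that stricter thresholds keep fewer genes by construction.

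Normexp gave 185 genes for the deletion without salt, 324 with salt, 1 for the interaction, 1667 in the salt overlap and 65 in the deletion overlap. It moved the median of all genes to −0.182 for salt in the deletion strain, 0.113 for the deletion without salt and −0.213 for the interaction. Signs changed there for GAL7 (−0.185, salt, deletion strain), ADE2 (−0.0456), TRP1 (0.0118), PRM9 (0.147), DSF1 (0.148) and other chromatin genes (0.00813) in the deletion without salt, and for YHR022C (−0.0321), MCO32 (−0.689), STL1 (−1.39) and the osmostress list (−0.276) in the interaction. With quantile scaling they changed for CLN2 (−0.0556, salt, wild type), ADE2 (−0.0162, no salt), LYS2 (0.00577, with salt), and STL1 (−0.17), GPP1 (−0.0079), HTZ1 (0.187) and the osmostress list (−0.0207) in the interaction. Median scaling gave 30 interaction genes and TRP1 at 0.0318 (no salt), LYS2 at 0.0106 (with salt) and ALD3 at 0.0905 (interaction). The authors' values gave 19 interaction genes, CLN2 at −0.025 (salt, wild type), ADE2 at −0.035 without and 0 with salt, ALD3 at 0.215 and HTZ1 at 0.19 (interaction), and glycolysis at −0.0075 (deletion, with salt). With no filter 14 interaction genes passed, and with all arrays above background the osmostress list was at −0.14. With only the groups compared, the deletion without salt gave 348 genes (223 higher, 125 lower) and the deletion overlap 214. At least 2-fold changes numbered 1303, 1354, 206 and 298 in the pairwise comparisons, and 228, 410 and 12 genes had adjusted p under 0.01 for the deletion without salt, with salt and the interaction.

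Without 1 array, with the lone array assumed to vary like the other groups, counts ran from 2284 to 3295 (salt, wild type), 2525 to 3096 (salt, deletion strain), 270 to 663 (deletion, no salt), 438 to 1435 (deletion, with salt) and 4 to 102 (interaction). The lowest of the last 3 were without wild-type unstressed replicate 1 and, for both others, without deletion salt replicate 1, and the 102 without wild-type salt replicate 1. Overlaps ran from 2077 to 2635 (salt) and 154 to 399 (deletion), and the osmostress interaction from −0.0965 to 0.172. Uncalled values crossed 0: ADE2 (−0.0982 to 0.109 without and −0.104 to 0.296 with salt), TRP1 (−0.251 to 0.224), YOL014W (−0.0394 to 0.348) and PLB3 (−0.15 to 0.569 without and −0.0012 to 0.274 with salt) in the deletion comparisons, STL1 (−0.00496 to 0.462), GPP1 (−0.0965 to 0.334) and ALD3 (−0.333 to 0.29) in the interaction, and CLN2 (−0.129 to 0.376) under salt in wild type.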

Other observations

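The tests of brightness, of repeated gene families and of neighbouring genes were chosen before their results were seen, while the test of another signal, the search for copies under other names and the repeats of these tests with other settings were chosen after, and the list of genes near chromosome ends was made after the files had been read.

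Several gene lists passed camera in none of the 5 comparisons. Under salt in wild type, 11 of 22 heat shock factor chaperone genes fell and 3 rose, or 13 and 4 adjusted over the list alone (median −0.37, camera adjusted p = 0.102). Of 20 G2/M genes 7 fell and 1 rose (−0.32, camera adjusted p = 0.0518), and of 74 mitochondrial ribosomal protein genes 12 rose and 5 fell, or 6 and 3 adjusted over the list alone (0.10). Of 22 cell wall genes 7 rose and 5 fell, of 16 pheromone response genes 5 rose and 3 fell, of 7 a-specific genes 4 fell and 1 rose, and of 5 alpha-specific genes 2 rose. Of 12 SWR1 complex genes 3 rose and 2 fell, or 2 and 2 adjusted over the list alone (0.21, camera adjusted p = 0.526), and of 14 INO80 complex genes 2 rose and 3 fell (−0.07, camera adjusted p = 0.524). In the unstressed deletion strain 1 SWR1 gene was higher and 1 lower (−0.21), and 1 INO80 gene was higher (−0.04). With salt 4 SWR1 genes were lower (−0.18), and 1 INO80 gene was higher and 2 lower, or 1 and 3 adjusted over the list alone (−0.14).

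Genes near chromosome ends were changed more often in the unstressed deletion strain. Of 218 such genes 61 (28%) changed, 28 higher and 33 lower, or 42 and 48 adjusted over the list alone, against 677 of 5176 others (13.1%; two-sided Fisher exact p = 1.44e-08 over genes, which are not independent). The count was 39 (17.9% against 4.46%) and 31 (14.2% against 4.91%) without wild-type unstressed replicates 1 and 2, 98 (45% against 25%) with the replicate block and 63 (29% against 14.7%) in the authors' values. In the main values 48 of 167 genes with a standard name changed near the ends (28.7%, against 12.4% elsewhere, two-sided Fisher exact p = 5.09e-08). Of 51 without a standard name 13 changed (25.5%, against 20.5% elsewhere, two-sided Fisher exact p = 0.466). Dim probes, taken by brightness alone, are argued against, as 10000 brightness-matched random sets held a median of 32 and at most 52 changed genes, a share of 1e-04, the smallest they can give, but another signal and its processing stay open: under normexp, which changes the signal and the background correction together, 4.13% changed against 3.4% (Fisher exact p = 0.566). Near-identical gene families are argued against only in part. A name stem was removed where more than 1 named gene tested near the ends bore it. Outside these stems 25 of 90 genes with a standard name changed (27.8%, against 12.3% of 4692 others, two-sided Fisher exact p = 8.43e-05). Other stems were kept even where genes elsewhere share them, as FIT2 and FIT3 do with FIT1. Of the 25, 5 (PRM9, MST28, DSF1, GEX2 and IMD2) have close copies but were not removed by stem. Without these 5, 20 of 85 genes changed (23.5%, two-sided Fisher exact p = 0.00435). All genes taken out were changed ones near the ends, and none was taken out elsewhere. This p is therefore not that of an even-handed removal. The share that stayed higher argues against the removed stems and these 5 genes as the whole explanation for genes with a standard name. Families with 1 named gene tested near the ends, other close copies and genes without a standard name were not sorted out in this way. For those the explanation stays open.

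With salt 22.5% of the genes near the ends changed against 21.9% of others (p = 0.867, Fisher exact), although whether the 2 conditions differ was not tested. Among genes near the ends chosen after their values were seen, the gluconeogenic PCK1 (−1.83) and the invertase SUC2 (−1.16) were lower in the unstressed deletion strain, and the iron uptake genes FIT1 (2.61), FRE2 (2.14) and ARN2 (1.85) and the hexokinase HXK1 (3.69) were higher.

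A hypothesis tested on the same calls is that neighbouring genes share the effect of the deletion. In the unstressed comparison 86 pairs of adjacent measured genes changed the same way, 41 higher and 45 lower, against a median of 48 and a highest value of 77 over 10000 shuffles, a share of 1e-04, the smallest they can give. There were 22 and 23 such pairs, against medians of 6 and 7, without wild-type unstressed replicates 1 and 2, and 231 against 172 with the replicate block. In the authors' values there were 89 against 61 (at most 91 in 1000 shuffles, share 0.002), and under normexp 10 against 5 (share 0.014). Pairs changed in opposite directions numbered 44, against a median of 48. Away from chromosome ends 70 pairs changed the same way, against a median of 42. Of the 86 pairs 51 were tandem, 22 divergent and 13 convergent, against 2509, 1371 and 1362 of all 5242 pairs. The effect of lacking Htz1 may thus extend over neighbouring genes, although shared regulation of neighbours and probes that read into a neighbour were not tested.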
